A study of Homo sapiens with 24 samples.

How the data were processed

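Bulk messenger RNA was sequenced from 24 human tissue samples, 8 of normal fat, 8 of well-differentiated liposarcoma (WDLPS) and 8 of dedifferentiated liposarcoma (DDLPS). Per the labels' protocols, tissue was kept in liquid nitrogen or a stabilisation solution, frozen pieces were homogenised, total RNA was extracted with a column kit, and polyadenylated RNA was captured on poly-T beads. The authors deposited 1 table of raw read counts per gene, with 1 column per sample and no normalisation. Per the submitters' processing notes, fastp, HISAT2 2.05 and featureCounts 1.5.0-p3 were used with genome build GRCh38. Their settings, the annotation release, the strand setting and the treatment of reads that map to several genes are not given in the sources used here.

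The deposited table held counts for 58735 genes, each with an Ensembl gene ID, a symbol and coordinates. For 27 genes a spreadsheet had turned the symbol into a date, and their symbols were taken from the gene ID. Another 4 older symbols were replaced by current ones in the same way. The 520 genes that comprise chromosome Y, XIST and TSIX were left out of all steps. Total counts ran from 14875151 to 23870237 per sample, and 13717 to 27814 genes had at least 1 read. A gene with 0 reads over the 8 libraries of a group was given a floor of 3 reads over the group, which was 0.0222 CPM (reads of a gene relative to the library size, on edgeR's scale) in normal fat, 0.0201 CPM in WDLPS and 0.0186 CPM in DDLPS. Floors and counting intervals cover counting error only, because the reads carry no molecular identifiers.

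Samples were grouped by the diagnosis in the labels. The labels do not say whether each sample came from a separate donor or which tumour and fat samples shared one, so p-values measure only the spread between these samples, and no pairing was used. Replicate numbers follow the order of the accessions and pair nothing. Within each group, libraries differed by more than counting noise, and none was merged with another.

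Gene tests were run with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr using the group, which left 17141. Library sizes were scaled by TMM, and 1 quasi-likelihood model with robust dispersion was fitted to all 24 samples with a mean per group. Each comparison was a two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. The common biological coefficient of variation was 0.853, and it was 0.905, 0.877 and 0.785 when estimated within normal fat, WDLPS and DDLPS alone. Group levels are means ± SD of CPM computed with the TMM-scaled library sizes.

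A total of 33 gene lists were fixed before the data were examined. They covered genes of the chromosome 12q amplicon, adipocyte identity, lipogenesis, fatty acid oxidation, the cell cycle, p53 targets, extracellular matrix, adipose progenitors, YAP targets, macrophages, T cells, cytotoxic and NK cells, regulatory T cells, B cells, plasma cells, dendritic cells, mast cells, neutrophils, MHC class I and class II, the responses to interferon gamma and interferon alpha, immune checkpoints, lymphoid chemokines, endothelium, pericytes and smooth muscle, skeletal muscle, epithelium and mesothelium, Schwann cells and nerve, erythroid cells, hypoxia and glycolysis, immediate early and stress genes, and insulin and PI3K signalling. List 34 held the protein-coding genes between 57 and 71 Mb of chromosome 12, a window that was also fixed in advance. Lists were tested with camera in limma 3.58.1, which asks whether a list stands apart from the other genes, with a preset inter-gene correlation of 0.01. Camera was repeated with the correlation estimated for each list, and fry was run as a test of whether a list moves one way. For each library a list score was the mean log2 CPM (prior count 2) of the list's tested members, and group means of scores were compared with exact two-sided permutation tests over all 12870 splits of 16 samples. The spread of scores in DDLPS against WDLPS was compared by exact permutation of the absolute deviations from the group median. Adjustment was over the 34 lists within a comparison.

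The genes named in the text followed a rule set at the same time. It took 21 key genes whatever their result, the 8 protein-coding genes with the largest rise and the 8 with the largest fall among changed genes with an average log2 CPM of at least 1 and with all samples of each group beyond the other group's median, and up to 4 members per list with the smallest adjusted p. Genes named outside that rule are marked as chosen after their values were seen. Single-gene results of 2 list members are not reported here, though both were tested and counted in their lists.

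The gene tests, camera and the score test were tried on simulated counts with known changes. No change of spread was planted, so the power of the spread test was not checked, and neither was that of fry. In the simulation of WDLPS against normal fat (16301 genes), 7.69% of genes with a log2 change of 1 were recovered, 50% of those with 2 and 71.2% of those with 3, with 1 false call among 86. In that of DDLPS against normal fat (16284 genes) the shares were 1.52%, 52.2% and 68.7%, with 0 false calls among 83. In that of DDLPS against WDLPS (16275 genes) they were 4.62%, 50.7% and 74.6%, with 4 false calls among 93. A planted list of 20 genes with a log2 change of 1 was found by camera, by camera with an estimated correlation and by the score test in all 3 simulations, with 0 false lists. Genes were drawn independently of each other there, so the 0 cannot show how often lists of genes that vary together are called.

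The alternatives set before the data were seen were DESeq2 size factors and upper-quartile scaling, the DESeq2 1.42.0 test, limma voom with sample quality weights, no filter and a stricter filter (at least 1 CPM in 8 samples), a fit of only the 2 groups compared, a non-robust fit, protein-coding genes only, a test against a fold change of 2, another prior count, scores from z-scores, and each library left out in turn. After the data were seen, a fit without the 2 libraries with under 15000 detected genes and a fit with detected genes as a covariate were added.

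Overlapping genes limit some counts. Against GENCODE release 29 exons, 96.6% of 475 protein-coding genes with at least 90% of their exonic bases shared on the same strand had under 100 reads in all, against 25.2% of 11057 genes that share none. The same held for 95.7% of 23 genes with such a share on the opposite strand only. CD68, a macrophage marker and a key gene, shares 85.8% of its exonic bases with other genes and had 34 reads over the 24 samples, so it was not tested. DERL3 shares 77.0%, on the opposite strand, and its values are uncertain for the same reason. Other named genes share less, such as ADIPOQ (46.2%), CEBPA (43.4%), CDK4 (43.2%), NEFM (38.9%), HEPACAM (37.5%) and B4GALNT1 (26.7%). Their shares lie on the opposite strand as well, and some of their reads may be missing. HBA1 and HBA2, SAA1, HSPA1B and TPSAB1 have near-identical copies, so their values are uncertain as well.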

Results

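RNA sequencing was used to compare 8 samples of normal fat, 8 of WDLPS and 8 of DDLPS, tumour types in which extra copies of chromosome 12q are common. WDLPS is the form that keeps fat-like cells, and DDLPS is the more aggressive form that has lost them. The study set human liposarcoma beside mouse models with regard to the immune cells in the tumours, and the human samples are described here. Total counts were 19678210 ± 2641095 in normal fat, 18622750 ± 1840834 in WDLPS and 17129280 ± 1159109 in DDLPS (mean ± SD, n = 8 each). Reads of mitochondrial genes made up 15.6 ± 6.31% of counts in normal fat, 13.7 ± 5.96% in WDLPS and 6.75 ± 2.69% in DDLPS. That share was lower in DDLPS than in normal fat (exact permutation p = 0.000777, adjusted p = 0.0131) and than in WDLPS (exact permutation p = 0.00761, adjusted p = 0.0400).

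**Figure D1:**
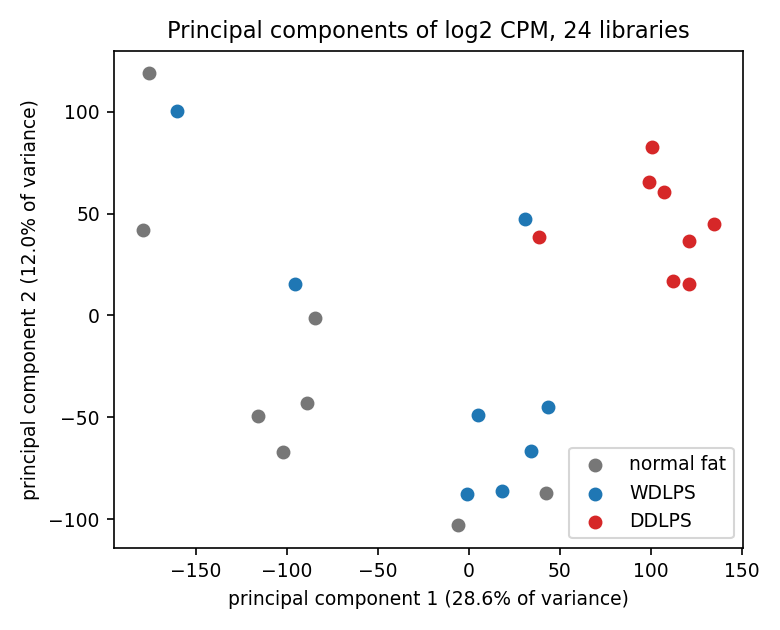
The first 2 principal components of log2 CPM are plotted for the 24 libraries, with 1 point per library and the share of variance on each axis. Component 1 holds 28.6% of the variance, and 7 of 8 DDLPS libraries lie beyond all WDLPS and normal fat libraries on component 1, which had a correlation of 0.750 with the number of genes detected per library.

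The first comparison was of WDLPS with normal fat. MDM2, which encodes the ubiquitin ligase that removes p53, rose from 44.4 ± 11.8 CPM in normal fat to 578 ± 325 CPM in WDLPS (log2 fold change 3.70, SE 0.41, adjusted p = 3.33e-05), and 8 of 8 WDLPS libraries lay above the highest normal fat library. CDKN2A, a tumour suppressor locus that restrains the cell cycle, rose by 4.51 (SE 0.82, adjusted p = 0.0231). COL5A1, a fibrillar collagen, and LOXL3, an enzyme that crosslinks collagen, rose by 2.69 (SE 0.53) and 2.32 (SE 0.43). The keratins KRT8 and KRT19, found in epithelium and mesothelium, fell by 6.61 (SE 1.23) and 10.12 (SE 1.91). In normal fat KRT8 had a median of 12.5 CPM and a highest level of 1199 CPM, and KRT19 had 1.87 and 487 CPM. The sizes of these falls thus lean on the highest libraries, though 7 and 8 of 8 normal fat libraries lay above all WDLPS libraries. ADIPOQ, the adipocyte hormone adiponectin, stood at 2513 ± 2093 CPM in WDLPS against 3524 ± 1947 CPM in normal fat and did not pass (log2 fold change -0.49, SE 1.25, adjusted p = 0.900).

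In total 31 of 17141 genes changed, 20 higher and 11 lower in WDLPS, while 2174 genes had an unadjusted p under 0.05. By the rule for named genes, which required all samples of each group beyond the other group's median, the other large rises were in MYRFL (6.89, SE 1.41), the DNA repair nuclease EXO1 (4.87, SE 1.04), RAB3IP (2.99, SE 0.62), the phospholipase PLB1 (2.30, SE 0.44) and CERCAM (2.03, SE 0.43). The topoisomerase TOP2A, a key gene, rose as well (3.27, SE 0.66). Besides the keratins, the tight junction gene CLDN1 fell by 7.30 (SE 1.47), BMP3 fell by 6.62 (SE 1.35), the collagen lysine hydroxylase PLOD2 fell by 2.25 (SE 0.44), CDC37L1 fell by 2.19 (SE 0.46), STRADB fell by 2.01 (SE 0.34) and ORMDL3, a regulator of sphingolipid synthesis, fell by 1.73 (SE 0.31). Adjusted p for these genes ran from 0.0231 to 0.0428. CDK4, a cell cycle kinase also on 12q, was at 460 ± 416 CPM in WDLPS and 84.5 ± 65.3 CPM in normal fat, with 5 of 8 WDLPS libraries above all normal fat libraries (log2 fold change 2.44, SE 0.67, adjusted p = 0.110). HMGA2, a chromatin protein of the same region, was at 45.9 ± 54.1 CPM against 0.755 ± 1.53 CPM, with 7 of 8 libraries above all normal fat libraries (5.92, SE 1.31, adjusted p = 0.0541). COL1A1 narrowly missed the threshold as well (3.02, SE 0.67, adjusted p = 0.0541).

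Of the 41 measured genes of the 12q amplicon list, 5 rose over all genes tested and 23 rose when adjusted over the list alone. They were MDM2, RAB3IP, SLC35E3 (3.90, SE 0.71), MARCHF9 (3.83, SE 0.72) and FRS2 (2.62, SE 0.55), the last named after its value was seen. Of 77 genes in the window from 57 to 71 Mb, 6 rose (the same 5 and MYRFL), or 25 adjusted over the list alone, and the median log2 fold change was 1.15 against 0.01 for the other 701 tested genes of chromosome 12. Per 1 Mb the rise was uneven within the window, with a median of -0.143 at 64 Mb (6 genes) and 2.62 at 69 Mb (7 genes). Some stretches outside it stood high as well, such as 76 Mb (6 genes) with a median of 1.17. Both lists stood higher than other genes by camera with the preset correlation and with an estimated one (adjusted p = 0.0120 for each with an estimated correlation). Their scores also rose by exact permutation (adjusted p = 0.0132 for each). WDLPS replicate 6, the lowest of its group in MDM2, had an amplicon score of 3.81 and a window score of 3.86, inside the range of normal fat (3.53 to 4.21 and 3.34 to 4.05).

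**Figure D2:**
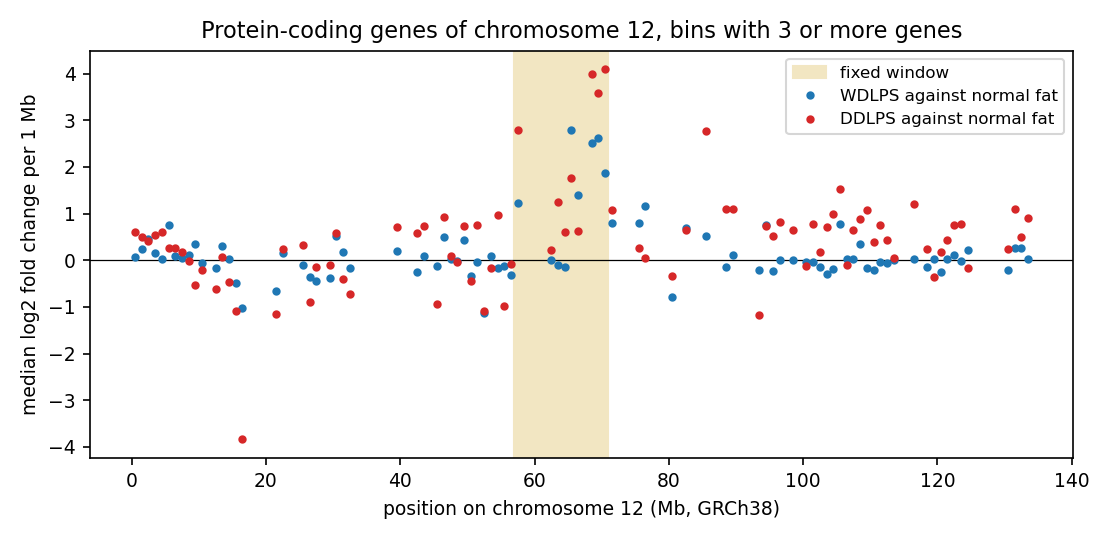
The median log2 fold change of protein-coding genes is plotted per 1 Mb of chromosome 12 for each tumour type against normal fat, with the window from 57 to 71 Mb shaded and bins of 3 or more tested genes shown. Medians over the whole window were 1.15 in WDLPS and 2.23 in DDLPS.

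Most proliferation and matrix genes were higher in WDLPS on average (38 of 40 and 26 of 27), and few passed. Of 40 cell cycle genes, 1 rose (TOP2A) and 12 did so adjusted over the list alone. The list rose by camera, and the adjusted p was 0.195 with an estimated correlation. E2F1 (2.01, SE 0.47, adjusted p = 0.0621) and MCM4 (1.44, SE 0.38, adjusted p = 0.0977) did not pass. Of 27 extracellular matrix genes, 1 rose (COL5A1) and 10 did so adjusted over the list alone, with adjusted p = 0.112 with an estimated correlation. The scores of these 2 lists did not pass (exact permutation adjusted p = 0.0702 for each). Of 23 p53 targets 0 passed in edgeR over all genes and 5 rose adjusted over the list alone, among which ZMAT3 had the smallest adjusted p over all genes (1.55, SE 0.41, adjusted p = 0.0969). The score of the p53 targets rose by 0.54 (exact permutation adjusted p = 0.0383, or adjusted p = 0.0655 with a prior count of 0.5), while camera gave adjusted p = 0.140 with an estimated correlation.

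Fat cell programmes did not separate WDLPS from normal fat gene by gene. Of 30 adipocyte identity genes 0 changed, also adjusted over the list alone, although all 30 were lower on average. The list was lower by camera (adjusted p = 0.316 with an estimated correlation) and its score did not pass (exact permutation adjusted p = 0.105). WDLPS replicate 1 had an adipocyte score of 2.03 against 7.76 to 8.88 in the other 7, and without it, a setting chosen after the data were seen, the mean difference from normal fat went from -1.35 to -0.56, and that of the lipogenesis score from -0.25 to 0.08. FABP4, the fatty acid carrier of adipocytes, stood at 3794 ± 3164 CPM against 10811 ± 10652 CPM (-1.51, SE 0.69, adjusted p = 0.353), and PPARG (-0.82, SE 0.49), PLIN1 (-0.87, SE 0.86) and CEBPA (-0.12, SE 0.57) did not pass. Lipogenesis genes gave 0 of 19, also adjusted over the list alone, and did not pass camera (adjusted p = 0.133). Fatty acid oxidation gave 0 of 22 and 5 lower adjusted over the list alone, with camera adjusted p = 0.000246 and adjusted p = 0.316 with an estimated correlation. Insulin and PI3K signalling gave 0 of 17, also adjusted over the list alone, with camera adjusted p = 0.00571 and adjusted p = 0.316 with an estimated correlation.

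Among the immune lists, only the macrophage score passed in WDLPS against normal fat, although the median log2 fold change was larger in other lists (1.99 in B cells against 0.87 in macrophages). Of 24 tested macrophage markers, 23 were higher on average, 0 passed over all genes and 4 rose adjusted over the list alone. The macrophage score rose from 5.37 ± 0.95 to 6.55 ± 0.32 (exact permutation adjusted p = 0.0497, or adjusted p = 0.0655 with a prior count of 0.5), and camera gave adjusted p = 2.78e-11, or adjusted p = 0.196 with an estimated correlation. CSF1R, the receptor for the growth factor of macrophages, was at 237 against 76.3 CPM (1.64, SE 0.37, adjusted p = 0.0591), and CD163 did not pass (0.75, SE 0.58). T cell markers gave 0 of 21 over all genes and 1 adjusted over the list alone. Their camera call (adjusted p = 3.18e-05) was lost with an estimated correlation (adjusted p = 0.322). CD3E (1.01, SE 0.78), CD8A (0.73, SE 0.64), FOXP3 (2.74, SE 1.12), PDCD1 (1.30, SE 1.23), CD274 (-0.14, SE 0.81) and the B cell marker MS4A1 (3.85, SE 1.66) did not pass. The B cell follicle chemokine CXCL13 had 3 reads in all of normal fat, and WDLPS was 207-fold higher (counting interval 70.4 to 1004), with adjusted p = 0.113.

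No member of the remaining immune lists passed over all genes in edgeR. Adjusted over the list alone, 2 of 7 B cell genes rose, 1 of 15 dendritic cell genes, 3 of 21 checkpoint genes and 1 of 15 lymphoid chemokine genes, and 0 passed among cytotoxic and NK cells (17 tested), regulatory T cells (11), plasma cells (11), mast cells (10), MHC class I (17) and class II (12) and the interferon gamma (23) and alpha (28) responses. Camera called 7 of them higher in WDLPS, and each call was lost with an estimated correlation, at which the adjusted p was 0.330 for cytotoxic and NK cells, 0.322 for regulatory T cells, B cells and immune checkpoints, 0.371 for dendritic cells, 0.316 for MHC class II and 0.354 for lymphoid chemokines. The interferon alpha response was also called higher by camera (adjusted p = 9.64e-06), with adjusted p = 0.365 with an estimated correlation. Plasma cells, mast cells, MHC class I and the interferon gamma response did not pass camera. Neutrophil genes were lower by camera (adjusted p = 0.000117, or adjusted p = 0.234 with an estimated correlation), with 0 of 15 over all genes and 5 lower adjusted over the list alone, S100A8 among the lowest (-3.15, SE 0.79, adjusted p = 0.0805).

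Markers of other tissue components moved as follows. Of 13 epithelial and mesothelial genes 2 fell, KRT8 and KRT19, or 5 adjusted over the list alone, and the camera call (adjusted p = 0.000153) had adjusted p = 0.196 with an estimated correlation. The score of that list did not pass (exact permutation adjusted p = 0.0799). All 4 measured erythroid genes were lower, each only adjusted over the list alone, and their score fell by 3.18 (exact permutation adjusted p = 0.0383), while camera gave adjusted p = 0.112 with an estimated correlation. HBB, a chain of haemoglobin, was at 181 CPM against 1396 CPM. Hypoxia and glycolysis (adjusted p = 0.234) and immediate early and stress genes (adjusted p = 0.371) lost their camera calls with an estimated correlation. Each held 0 changed genes (of 19 and 21), while 2 hypoxia and 1 immediate early gene were lower adjusted over the list alone. Endothelium (22 genes), pericytes and smooth muscle (17), skeletal muscle (8), Schwann cells and nerve (8), adipose progenitors (20) and YAP targets (16) held 0 changed genes in edgeR and did not pass camera. Adjusted over the list alone, 1 YAP target was higher and 1 Schwann and nerve gene lower.

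The 31 calls depended on single libraries. Leaving out each of 16 libraries in turn gave 10 to 177 genes, with MDM2, CDKN2A, LOXL3, STRADB and ORMDL3 past the threshold each time, while TOP2A was lost in 9 of the 16 fits and EXO1 in 11.

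**Figure D3:**
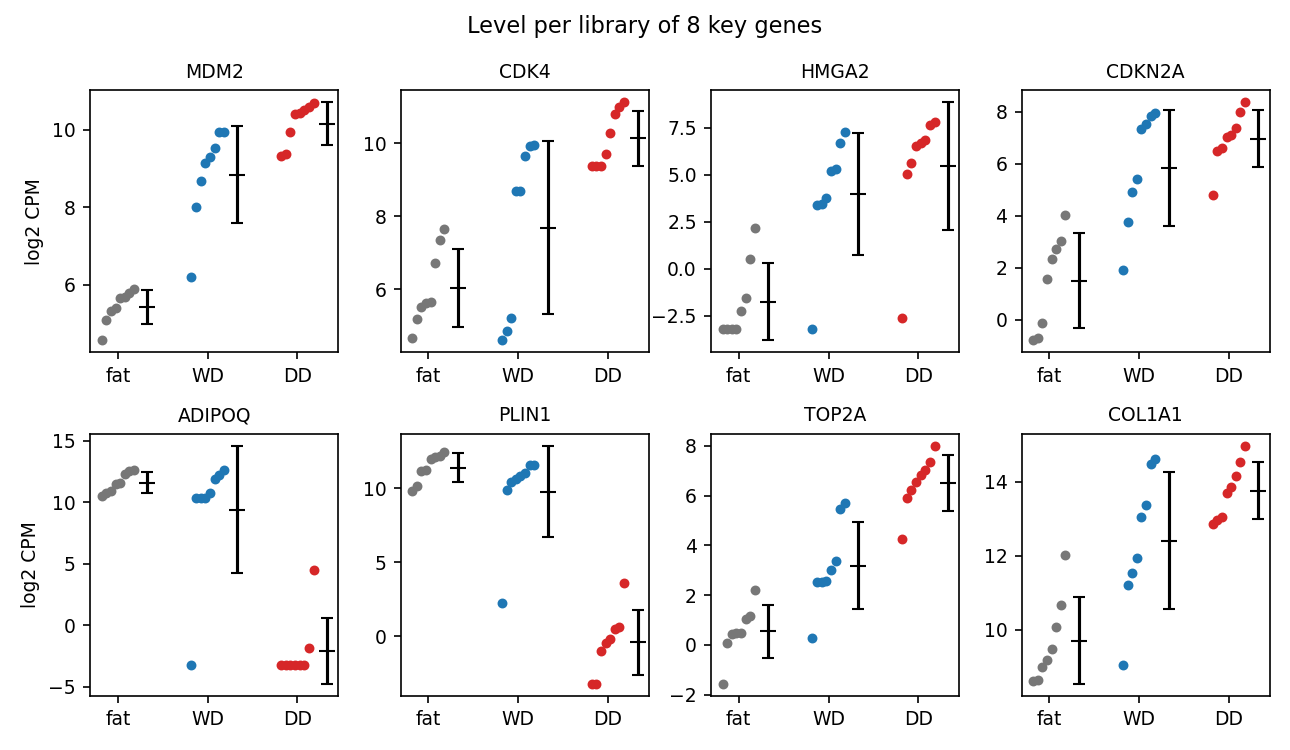
Log2 CPM (TMM-scaled, prior count 2) of 8 key genes is plotted per library for normal fat (fat), WDLPS (WD) and DDLPS (DD), with 1 point per library, ordered by value, and the group mean ± SD as a bar. MDM2 lies above all normal fat libraries in 8 of 8 WDLPS and 8 of 8 DDLPS libraries, and ADIPOQ and PLIN1 lie below all normal fat libraries in 8 of 8 DDLPS libraries.

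The second comparison was of DDLPS with normal fat, where adipocyte identity genes fell. ADIPOQ fell from 3524 ± 1947 to 2.72 ± 7.63 CPM (log2 fold change -10.34, SE 1.86, adjusted p = 0.000317), and the lipid droplet coat gene PLIN1 fell from 3149 ± 1705 to 2.07 ± 4.07 CPM (-10.57, SE 1.29, adjusted p = 4.22e-06). PPARG and CEBPA, the transcription factors that drive fat cell formation, fell by 3.46 (SE 0.54) and 4.14 (SE 0.65). MDM2 rose to 1208 ± 394 CPM (4.76, SE 0.43, adjusted p = 9.92e-08), CDK4 rose to 1271 ± 659 CPM (3.91, SE 0.71, adjusted p = 0.00037) and HMGA2 rose to 102 ± 78.2 CPM (7.07, SE 1.37, adjusted p = 0.000666). The proliferation markers TOP2A and MKI67 rose by 6.06 (SE 0.75) and 5.93 (SE 1.18).

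In total 3938 genes changed, 1696 higher and 2242 lower. By the rule for named genes the largest falls were in the lipid droplet gene CIDEC (-14.25, SE 1.10), the glycerol-phosphate dehydrogenase GPD1 (-12.39, SE 1.03), PCK1 of glyceroneogenesis (-12.27, SE 1.09), the acute-phase gene SAA1 (-12.75, SE 1.63), leptin LEP (-12.68, SE 1.46) and TRARG1, a regulator of glucose transporter traffic (-11.48, SE 1.35). THRSP, a lipogenic nuclear protein, had 3 reads in all DDLPS libraries and was 19885-fold lower (counting interval 6804 to 96429). HEPACAM had 0 reads in DDLPS and was at least 1037-fold lower. By the same rule the largest rises were in B4GALNT1, a ganglioside synthase of 12q (8.07, SE 1.47), the developmental transcription factor LHX9 (7.51, SE 1.31), the retinol transporter STRA6 (7.50, SE 1.35), the glutamate receptor GRIK1 (7.32, SE 1.72) and CYP27B1 of vitamin D activation, also of 12q (7.28, SE 1.31). NEFM, a neurofilament, and the transcription factor ZIC4 had 0 reads in normal fat and were at least 492-fold and at least 370-fold higher. CDKN2A rose by 4.94 (SE 0.84), COL1A1 rose by 3.74 (SE 0.69), and the stress kinase MAP3K5 fell by 1.64 (SE 0.49, adjusted p = 0.0166). JUN did not pass (0.24, SE 0.61, adjusted p = 0.802).

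All 30 adipocyte identity genes fell, among them the insulin-responsive glucose transporter SLC2A4 (-6.84, SE 0.61), and all 30 did so adjusted over the list alone. The list was lower with the preset correlation and with an estimated one (adjusted p = 0.00781 with an estimated correlation). Of 19 lipogenesis genes 11 fell, also adjusted over the list alone, including AGPAT2 (-5.82, SE 0.58), PC (-4.69, SE 0.53) and GPAM (-6.25, SE 0.77), with adjusted p = 0.0998 with an estimated correlation. Of 22 fatty acid oxidation genes 15 fell, also adjusted over the list alone, led by the carnitine carrier SLC25A20 (-2.67, SE 0.33) and HADH (-3.98, SE 0.53), with adjusted p = 0.0712 with an estimated correlation. The share of mitochondrial reads fell alongside, from 15.6 ± 6.31% to 6.75 ± 2.69%. Of 17 insulin and PI3K genes 8 fell, or 10 adjusted over the list alone, including PDE3B (-5.97, SE 0.85), with adjusted p = 0.0712 with an estimated correlation. Of 19 hypoxia and glycolysis genes 7 fell and 1 rose (KDM3A, named after its value was seen), or 8 and 1 adjusted over the list alone, with PFKFB3 (-4.09, SE 0.61) and HK2 (-4.29, SE 0.65) foremost and adjusted p = 0.150 with an estimated correlation.

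On chromosome 12, 29 of 41 amplicon genes rose and 1 fell (29 and 2 adjusted over the list alone), including SLC35E3 (5.32, SE 0.76), MARCHF9 (5.06, SE 0.76) and FRS2 (3.61, SE 0.57). Of the 77 window genes 45 rose and 3 fell (47 and 5 adjusted over the list alone), and the monocarboxylate transporter SLC16A7 fell by 3.59 (SE 0.57). The window median was 2.23 against 0.21 for the rest of the chromosome, and both lists held with an estimated correlation (adjusted p = 0.0315 for each). Of 40 cell cycle genes 37 rose, or 38 adjusted over the list alone, including MCM4 (2.84, SE 0.40), E2F1 (3.34, SE 0.49) and BIRC5 (4.47, SE 0.75), with adjusted p = 0.0712 with an estimated correlation. Of 27 matrix genes 17 rose, or 21 adjusted over the list alone, including COL5A1 (3.99, SE 0.56), COL1A2 (3.05, SE 0.52) and COL3A1 (3.21, SE 0.56), with adjusted p = 0.0998 with an estimated correlation. Of 23 p53 targets 7 rose and 4 fell, also adjusted over the list alone, with BAX higher (1.44, SE 0.28) and PHLDA3 (-1.48, SE 0.33) and BTG2 (-2.19, SE 0.54) lower, and camera did not pass (adjusted p = 0.322), while the score rose by 0.42 (exact permutation adjusted p = 0.0464, or adjusted p = 0.0756 with z-scores). The scores of the amplicon, the window, the cell cycle and the matrix rose and those of adipocyte identity, lipogenesis, fatty acid oxidation and insulin and PI3K signalling fell (exact permutation adjusted p = 0.000587 for each), as did that of hypoxia and glycolysis (adjusted p = 0.00432).

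Immune lists were compared next. Of 24 macrophage genes 4 rose, or 3 adjusted over the list alone, namely CSF1R (1.46, SE 0.37), FCGR1A (2.32, SE 0.71), FCGR3A (2.09, SE 0.66) and SIGLEC1 (1.35, SE 0.47), of which SIGLEC1 was lost in 11 of 16 fits that left out 1 library. The camera call for that list (adjusted p = 0.0328) was lost with an estimated correlation (adjusted p = 0.700), and CD163 did not pass (0.40, SE 0.58). Of 28 interferon alpha response genes 5 rose, namely IFI44 (1.98, SE 0.52), DDX60, HERC6, OAS3 and OASL (the last named after its value was seen), or 1 adjusted over the list alone, with camera adjusted p = 0.00697 and adjusted p = 0.700 with an estimated correlation. Of 21 checkpoint genes 4 rose, or 5 adjusted over the list alone, namely NT5E (1.71, SE 0.32), CD276 (1.76, SE 0.34), TIGIT (3.12, SE 1.09) and ENTPD1 (0.94, SE 0.34), and camera did not pass (adjusted p = 0.0846). NT5E is also in the YAP target list and TIGIT in the regulatory T cell list. Bulk RNA does not tell which cells of the tissue express a gene of these lists. Of 21 T cell genes 2 rose, CD28 (1.62, SE 0.39) and CD7 (2.51, SE 0.90), or 1 adjusted over the list alone. Of 11 regulatory T cell genes TIGIT and FOXP3 rose (FOXP3 by 3.14, SE 1.14, adjusted p = 0.0471), or 0 adjusted over the list alone, and FOXP3 was lost in 12 of 16 fits that left out 1 library. CD3E (0.85, SE 0.78), CD8A (1.13, SE 0.64), MS4A1 (0.36, adjusted p = 0.885), PDCD1 (2.92, SE 1.29) and CD274 (-0.15, SE 0.81) did not pass.

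The remaining immune lists did not pass camera in DDLPS against normal fat except neutrophils, of which 8 of 15 genes fell, or 10 adjusted over the list alone, including S100A8 (-4.58, SE 0.85) and AQP9 (-5.37, SE 1.00), with adjusted p = 0.267 with an estimated correlation. The neutrophil score fell by 2.44 (exact permutation adjusted p = 0.00317), and no other immune score passed. Of 7 B cell genes TNFRSF13C rose and BANK1 fell, also adjusted over the list alone. Of 11 plasma cell genes 3 rose, also adjusted over the list alone, namely DERL3, SDC1 and MZB1, and MZB1 was above the normal fat median in only 3 of 8 DDLPS libraries. Of 15 dendritic cell genes FSCN1 rose (2.19, SE 0.45). Of 15 lymphoid chemokine genes CCL2 fell (-2.64, SE 0.68), and CXCL13 was 263-fold higher (counting interval 89.6 to 1276, adjusted p = 0.00856). Each of the dendritic cell and chemokine counts was the same adjusted over the list alone. Of 17 MHC class I genes TAPBP rose and ERAP1 fell, also adjusted over the list alone. Of 23 interferon gamma response genes GBP5 and APOL1 rose, or 0 adjusted over the list alone. Cytotoxic and NK cells (17 genes), mast cells (10) and MHC class II (12) held 0 changed genes in edgeR, also adjusted over the list alone.

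Some endothelial and pericyte markers and all 4 erythroid markers were lower in DDLPS than in normal fat. Of 22 endothelial genes 8 fell, also adjusted over the list alone, including VWF (-1.82, SE 0.42) and CLDN5 (-2.93, SE 0.65), with adjusted p = 0.400 with an estimated correlation. Of 17 pericyte and smooth muscle genes 5 fell, or 6 adjusted over the list alone, including MCAM (-2.61, SE 0.53) and RGS5 (-2.14, SE 0.52), with adjusted p = 0.425 with an estimated correlation. All 4 erythroid genes fell, also adjusted over the list alone, with HBB at 11.5 CPM against 1396 CPM and adjusted p = 0.0712 with an estimated correlation. Of 13 epithelial and mesothelial genes 7 fell, including CALB2 (-6.51, SE 1.25), or 8 fell and 1 rose adjusted over the list alone, with adjusted p = 0.425 with an estimated correlation. Of 21 immediate early and stress genes 8 fell, or 13 adjusted over the list alone, including SOCS3 (-3.93, SE 0.81) and FOSB (-4.26, SE 1.02), with adjusted p = 0.503 with an estimated correlation. Adipose progenitors (DLK1 rose and 4 fell among 20, including ANXA3 and PCOLCE2), YAP targets (NT5E and TGFB2 rose and 3 fell among 16, including CRIM1 and F3) and Schwann and nerve genes (L1CAM and NCAM1 rose and 1 fell among 8) did not pass camera, nor did skeletal muscle, in which TNNT3 rose. Adjusted over the list alone, the progenitor and YAP counts were the same, 2 Schwann and nerve genes rose and 2 fell, and 0 muscle genes passed. By exact permutation the scores of endothelium (adjusted p = 0.0228), pericytes and smooth muscle (0.0464), erythroid cells (0.000587), epithelium and mesothelium (0.0228), adipose progenitors (0.0464) and Schwann cells and nerve (0.0423) fell and that of skeletal muscle rose (0.0423), while YAP targets and immediate early and stress genes did not pass. With scores made from z-scores, those of pericytes and smooth muscle, epithelium and mesothelium, skeletal muscle, Schwann cells and nerve, and adipose progenitors did not pass either (adjusted p from 0.0756 to 0.148).

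Leaving out each library in turn gave 3112 to 4937 genes, and of the key and largest genes only FOXP3 and GRIK1 lost their calls in any such fit, GRIK1 without DDLPS replicate 4. Among list members, CD7 was lost in 12 of 16 such fits, SDC1 and TNNT3 in 11, APOL1, ENTPD1 and OAS3 in 10, TIGIT and MZB1 in 8, and HERC6 and NCAM1 in 7. With a test against a fold change of 2 the count was 1163.

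The third comparison was of DDLPS with WDLPS, in which fat cell genes were again lower. ADIPOQ fell from 2513 ± 2093 to 2.72 ± 7.63 CPM (-9.85, SE 1.83, adjusted p = 0.00137), PLIN1 fell by 9.70 (SE 1.25), PPARG fell by 2.64 (SE 0.52) and CEBPA fell by 4.02 (SE 0.64). TOP2A rose from 16.6 ± 19.7 to 114 ± 72.7 CPM (2.79, SE 0.64, adjusted p = 0.00880). MDM2 (1.06, SE 0.38, adjusted p = 0.100), CDK4 (1.47, SE 0.65, adjusted p = 0.203) and HMGA2 (1.15, SE 1.05, adjusted p = 0.602) were higher in DDLPS on average and did not pass. The immune markers CD163, CD3E, CD8A, MS4A1, FOXP3, PDCD1 and CD274 did not pass either, with adjusted p between 0.231 and 0.998.

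In total 912 genes changed, 283 higher and 629 lower. By the rule for named genes the largest falls were again in CIDEC (-13.52, SE 1.08), PCK1 (-12.18, SE 1.09), GPD1 (-11.79, SE 1.01), LEP (-11.62, SE 1.41), TRARG1 (-10.85, SE 1.33) and SAA1 (-10.20, adjusted p = 0.000115). THRSP was 13233-fold lower (counting interval 4528 to 64169) and HEPACAM at least 694-fold lower. The dopamine transporter SLC6A3 had 0 reads in WDLPS and was at least 1135-fold higher in DDLPS. Other large rises by that rule were in BCAS1 (8.93, SE 1.80), STRA6 (7.28, SE 1.33), the heparan sulfate sulfotransferase HS6ST2 (6.20, SE 1.48), VEPH1 (5.36, SE 1.20), the basement membrane gene FRAS1 (5.06, SE 1.23), the protocadherin PCDH10 (4.84, SE 1.43) and the growth factor BMP7 (4.72, SE 0.93). MKI67 (2.91, SE 1.02, adjusted p = 0.0979), CDKN2A (0.43, SE 0.71), COL1A1 (0.72, SE 0.62), JUN (-0.56, SE 0.61) and MAP3K5 (-0.26, SE 0.47) did not pass.

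Of 30 adipocyte identity genes 28 fell, or 30 adjusted over the list alone, and the list held with an estimated correlation (adjusted p = 0.00111). Of 19 lipogenesis genes 11 fell, or 12 adjusted over the list alone, including the desaturase SCD (-6.51, SE 0.96) and AGPAT2 (-4.87, SE 0.55). Of 22 fatty acid oxidation genes 11 fell, or 14 adjusted over the list alone, including SLC25A20 (-2.36, SE 0.32), and the share of mitochondrial reads was lower as well. Of 17 insulin and PI3K genes 6 fell, also adjusted over the list alone, including SLC2A4 (-5.95, SE 0.59) and CAV1 (-2.31, SE 0.49). Of 40 cell cycle genes 10 rose, or 36 adjusted over the list alone, including CCNB1 (2.14, SE 0.51) and UBE2C (3.83, SE 0.95). For lipogenesis, fatty acid oxidation, insulin and PI3K signalling and the cell cycle the adjusted p was 0.0741 with an estimated correlation, and each score differed by exact permutation (adjusted p from 0.00264 to 0.00740).

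Of 41 amplicon genes 7 rose and 1 fell (16 and 2 adjusted over the list alone), with MARS1 (2.78, SE 0.66) and CTDSP2 (1.54, SE 0.40) higher and the carboxypeptidase M gene lower (-3.32, SE 0.60). The camera call had adjusted p = 0.280 with an estimated correlation. Of the 77 window genes 12 rose and 2 fell (21 and 4 adjusted over the list alone), with DTX3 foremost among the rises (4.19, SE 0.81) and adjusted p = 0.257 with an estimated correlation. Of 27 matrix genes THBS2 rose (2.73, SE 0.75), also adjusted over the list alone, and that list's camera call had adjusted p = 0.572 with an estimated correlation. Of 23 p53 targets PHLDA3 and BTG2 fell, also adjusted over the list alone. Of 16 YAP targets NT5E and AXL rose and CRIM1 fell, also adjusted over the list alone. Of 20 adipose progenitor genes PCOLCE2 fell, while 4 rose and 2 fell adjusted over the list alone. Camera did not pass for these 3 lists.

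Few genes of the immune lists differed between the tumour types. In edgeR 0 genes changed among macrophages (24 tested), T cells (21), cytotoxic and NK cells (17), regulatory T cells (11), plasma cells (11), dendritic cells (15), mast cells (10), MHC class II (12), the interferon gamma (23) and alpha (28) responses and lymphoid chemokines (15), and the same held adjusted over each list alone. The B cell adaptor BANK1 (-3.15, SE 0.85), ERAP1 of antigen processing (-1.54, SE 0.28) and AQP9 of the neutrophil list (-3.26, SE 0.91) fell, and NT5E of the checkpoint list rose (1.52, SE 0.31). Each was the only change in the immune list that held it, also adjusted over the list alone. NT5E is in the YAP target list as well. Camera placed macrophages, cytotoxic and NK cells, mast cells, neutrophils and MHC class II lower in DDLPS, and each call was lost with an estimated correlation, at which the adjusted p was 0.719, 0.572, 0.386, 0.545 and 0.607. No immune score passed by exact permutation, and the smallest adjusted p was 0.0567, for mast cells (0.23 ± 2.04 against 2.68 ± 1.29).

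Of 22 endothelial genes VWF fell (-1.81, SE 0.42), or 6 fell adjusted over the list alone, with adjusted p = 0.257 with an estimated correlation. Of 17 pericyte and smooth muscle genes MCAM (-2.61, SE 0.53), RGS5 (-2.09, SE 0.52) and TAGLN (-1.97, SE 0.51) fell, or 7 adjusted over the list alone, and the score fell by 1.30 (exact permutation adjusted p = 0.0309), while camera gave adjusted p = 0.180 with an estimated correlation. All 4 erythroid genes fell, also adjusted over the list alone, with adjusted p = 0.180 with an estimated correlation, and the score fell by 2.94 (exact permutation adjusted p = 0.0159). HK2, PFKFB3 and NDRG1 of the hypoxia and glycolysis list fell (3 of 19, or 5 adjusted over the list alone), with adjusted p = 0.387 with an estimated correlation, and the score fell by 0.45 (exact permutation adjusted p = 0.0396, or adjusted p = 0.0802 with z-scores). FOSB and BTG2 of the immediate early list fell (2 of 21, or 4 adjusted over the list alone), with adjusted p = 0.612 with an estimated correlation. CALB2 of the mesothelial list fell (-5.57, SE 1.20), ERBB3 and L1CAM rose and 1 fell among 8 Schwann and nerve genes, and TNNT1 rose among muscle genes, also adjusted over each list alone, without a camera call for those lists. Leaving out each library in turn gave 635 to 1146 genes. PCDH10 was lost in 10 of 16 such fits, L1CAM in 12, ERBB3 and PCOLCE2 in 11, ALAS2 in 10, BTG2 in 9, TNNT1 in 8, THBS2 and AQP9 in 6 and BANK1 in 5. HS6ST2 was lost without DDLPS replicate 1 and FRAS1 without DDLPS replicate 3.

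**Figure D4:**
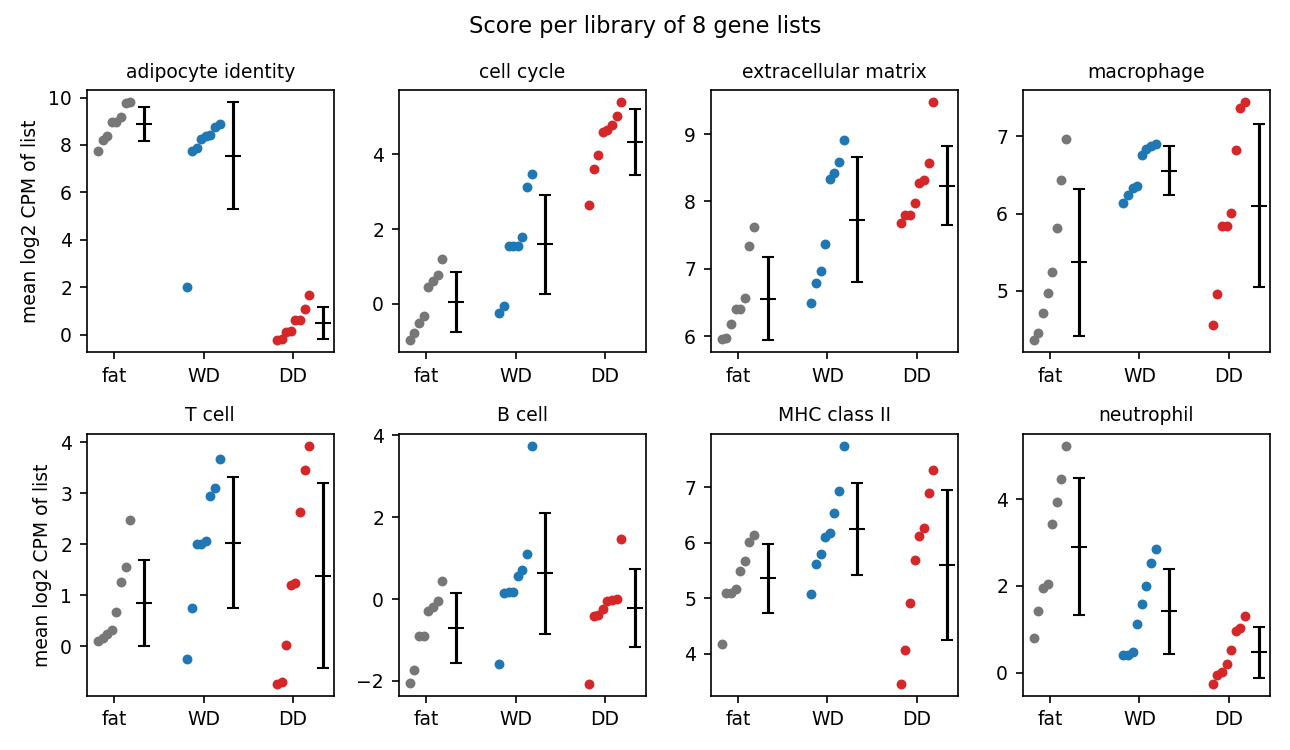
The score of 8 gene lists, the mean log2 CPM of a list's tested members, is plotted per library for normal fat (fat), WDLPS (WD) and DDLPS (DD), with 1 point per library, ordered by value, and the group mean ± SD as a bar. Adipocyte scores were 8.88 ± 0.73, 7.54 ± 2.26 and 0.48 ± 0.67, and macrophage scores were 5.37 ± 0.95, 6.55 ± 0.32 and 6.10 ± 1.05.

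The series title speaks of a heterogeneous immune microenvironment, so the spread of list scores between tumours was compared as well. Macrophage scores had an SD of 1.05 in DDLPS and 0.32 in WDLPS (exact permutation p = 0.0364), and MHC class I scores had an SD of 0.78 and 0.32 (exact permutation p = 0.0194). Matrix scores spread less in DDLPS, with an SD of 0.59 against 0.93 (exact permutation p = 0.0420). These 3 lists had an unadjusted p under 0.05, and 0 of 34 lists passed after adjustment by the exact permutation test (smallest adjusted p = 0.439) or with scores made from z-scores (smallest adjusted p = 0.472). T cell scores had an SD of 1.82 in DDLPS and 1.28 in WDLPS. By the mean absolute deviation from the group median, 19 of 34 lists spread more in DDLPS. All immune lists did so except B cells (0.57 against 0.90 in WDLPS) and neutrophils (0.49 against 0.82). The lists share the same samples and were not tested as a set.

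The tumour types were also compared through their changes from normal fat. Of the 31 genes changed in WDLPS, 31 changed in DDLPS in the same direction, including MDM2, CDKN2A, TOP2A, COL5A1, KRT8 and KRT19, where independent lists would share 1.98 higher and 1.44 lower genes. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.672 and a covariance of 1.11. Unchanged groups simulated against the same normal fat libraries gave a correlation of 0.5 (0.484 to 0.516 over 20 simulations), a covariance of 0.240 and 0 genes called in both by edgeR. No change was simulated, so the 0 was set in advance and is no test of the 31 shared genes. The correlation and covariance show what shared normal fat libraries give by themselves. With the normal fat libraries split 4 and 4 over 20 splits, the correlation was 0.417 (0.283 to 0.511), the covariance 0.963 and the median number of genes called in both 6 (1 to 208).

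Median, mean and test of a list differed in sign in 10 cases, 6 in DDLPS against normal fat (adipose progenitors, cytotoxic and NK cells, dendritic cells, mast cells, MHC class I and lymphoid chemokines) and 4 in DDLPS against WDLPS (adipose progenitors, MHC class I, skeletal muscle, and Schwann cells and nerve). None of these lists passed camera there.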

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

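In this part, the test that left out the 2 libraries with the fewest detected genes, the covariate, the leave-one-out comparison and the tests of the rest of chromosome 12 and of the epithelial and mesothelial genes were chosen after the results were seen.

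A sample far from the others of its group was sought with Dixon's ratio, the gap to the nearest sample over the range of the group, at its 95% critical value. It marked 15 of 183 groups of values (8.20%), and 6 of the 15 came from 1 library. Chance marks about 1 in 20 (5%) of groups of independent normal values. The values here were not independent, and most libraries had 0 reads for ADIPOQ in DDLPS and for MS4A1 in normal fat. The 2 shares can therefore not be compared. In WDLPS, 1 library stood low for the adipocyte score (2.03 against the next 7.76, ratio 0.836), the lipogenesis score (5.09 against 6.99, ratio 0.541) and log2 CPM of ADIPOQ (ratio 0.856), PLIN1 (ratio 0.821), PPARG (ratio 0.629) and HMGA2 (ratio 0.631), of which the first 5 came from WDLPS replicate 1 and HMGA2 from replicate 6. Replicate 1 thus held little of the fat cell programme that the other 7 libraries held. Also in WDLPS, 1 library stood high for total count (22634930 against 19290170, ratio 0.543), the share of immunoglobulin reads (0.303% against 0.123%, ratio 0.597), the interferon alpha score (6.84 against 5.21, ratio 0.532) and MS4A1 (ratio 0.584), not the same library for all 4. In DDLPS, again not the same library throughout, 1 stood high for the share of immunoglobulin reads (3.46% against 0.0848%, ratio 0.976) and for ADIPOQ (ratio 0.829), and low for HMGA2 (ratio 0.733) and the chromosome 12 window score (4.54 against 5.30, ratio 0.564). In normal fat, 1 library stood high for MS4A1 (ratio 0.557). No explanation was tested for these values.

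Few genes passed in WDLPS against normal fat. Without the 2 libraries with the fewest detected genes the count was 23, but it was 96 without 1 of them, WDLPS replicate 3, 21 without the other and 117 with the number of detected genes as a covariate, so whether they add to the spread cannot be told apart from the loss of samples. Without normal fat replicate 8 it was 177, so single libraries that lie far from their group could add to the spread. Replicate 8 had 27814 detected genes and lay at 42.6 on component 1. Replicate 7, the next normal fat library in both, had 21148 and lay at -5.96. The SD of log2 fold changes beyond their standard errors was 0.683 in WDLPS (0.598 to 0.855 with each library left out). It was 1.44 to 1.66 in DDLPS with each library left out, so by this measure WDLPS lay nearer to normal fat. A single library as the source of the whole gap to DDLPS is argued against. Leaving out each in turn gave 10 to 177 genes in WDLPS and 3112 to 4937 in DDLPS. How much library spread and nearness each add to the few calls stays open.

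Genes of the chromosome 12 window stood higher in both tumour types. A shift of the whole chromosome or of the scaling is argued against by the rest of chromosome 12, with a median log2 fold change of 0.209 in DDLPS against 2.23 in the window. The highest median among 204 other windows of 14 Mb was 0.514 in WDLPS, below the 1.15 of this window. A local gain of the region that differs between tumours could account for the pattern, since neighbouring genes of the window varied together across tumours (mean correlation 0.242, with 7 of 204 windows as high). Copy number was not measured.

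Some epithelial and mesothelial genes stood higher in normal fat, with 2 of 13 lower in WDLPS and 7 in DDLPS. The camera calls were lost with an estimated correlation (adjusted p = 0.196 and 0.425), and the score passed in DDLPS (adjusted p = 0.0228, or adjusted p = 0.0756 with z-scores) and not in WDLPS (adjusted p = 0.0799). A single normal fat library as the whole source is argued against, since the score of the list, which was fixed in advance, differed by -1.60 or further from 0 in WDLPS (largest exact permutation p = 0.0275, unadjusted) and by -1.93 or further in DDLPS (largest exact permutation p = 0.0123, unadjusted) whichever normal fat library was left out. This test replaced a first one on KRT19, a gene chosen for its fall. Levels were uneven among normal fat libraries, with UPK3B at a median of 1.43 CPM and a highest level of 410 CPM. UPK3B, MSLN, BNC1 and WT1 each lay above all WDLPS libraries in only 2 normal fat libraries, against 7 for KRT8 and 8 for KRT19. A source in a few normal fat libraries therefore stays open. Mesothelial cells in the normal fat samples could account for part of it, with a median log2 fold change over 9 mesothelial genes of -4.43 in WDLPS and -6.04 in DDLPS. These 9 include the keratins that showed the pattern, and only KRT8 and KRT19 of them passed in WDLPS. CALB2 did not follow in WDLPS (-0.95, adjusted p = 0.731) and fell in DDLPS (-6.51, adjusted p = 0.000611). Epithelium of another organ could not be told apart, since the highest level of CDH1 or EPCAM in any normal fat library was 31.1 CPM against 1199 CPM for KRT8, between the bounds set for the test. That test replaced a first one on 5 epithelial genes, of which only CLDN4 had been tested for change.

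Other splits of the same samples were compared with the labels, with 100 splits per comparison that included the real one, as do the counts below. For WDLPS against normal fat, chance could not be excluded for the 31 genes, since 5 splits gave as many and the highest other gave 590, which points to a structure of the samples whose nature was not tested. With 100 splits, 1 is the smallest result possible, so chance can be argued against but not excluded. It was argued against for the 23 lists of camera with the preset correlation (1 split, with 21 the highest other), by a narrow margin. The count was also 21, as high as that other split, with DESeq2 size factors or the stricter filter. It was 2 with an estimated correlation, and no splits were run for these settings. For DDLPS against normal fat chance was argued against for the 3938 genes (1 split, 1424 the highest other) and not for the 17 lists (20 splits, 24 the highest other). For DDLPS against WDLPS it was argued against for the 912 genes (1 split, 102 the highest other) and not for the 18 lists (16 splits, 25 the highest other).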

How the results depend on the processing

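In this part, the fit without the 2 libraries with the fewest detected genes, the fit with detected genes as a covariate, and list score differences with 1 library left out, were chosen after the data were seen. No named gene or list changed direction while it passed with or without the setting. Signs differed in 45 of 13200 values of named genes and, between camera and fry, in 3 of 102 list tests (cytotoxic and NK cells, dendritic cells and lymphoid chemokines in DDLPS against normal fat), none of which passed. The larger direction of a count changed in places. WDLPS against normal fat had 20 genes higher and 11 lower, but 8 and 11 without normal fat replicate 2, 11 and 14 without replicate 7 and 8 and 8 without replicate 1. DDLPS against normal fat had 1696 higher and 2242 lower, but 3164 and 2779 with voom and 2596 each with the DESeq2 test. Of the 3938 genes, 6 had the other sign with the DESeq2 test and 6 with voom. For the changes below the cause was not tested, except that fits with fewer samples hold less information by construction.

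The count for WDLPS against normal fat moved most. In place of 31 genes, the DESeq2 test gave 433, voom 1074, no filter 18, a fit of the 2 groups only 9, a test against a fold change of 2 gave 1, and the covariate gave 117. Of the 31, these shared 31 (DESeq2), 19 (voom), 17 (no filter), 8 (2 groups) and 31 (covariate). DESeq2 size factors, upper-quartile scaling, the stricter filter, the non-robust fit, protein-coding genes only and the fit without the 2 libraries gave 23 to 41. Leaving out 1 library gave 10 to 177: 16, 19, 15, 12, 17 and 177 without normal fat replicates 1, 2, 3, 4, 5 and 8, and 10, 96, 19, 15, 64 and 12 without WDLPS replicates 1, 3, 4, 5, 6 and 8.

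For DDLPS against normal fat, voom gave 5943 and the test against a fold change of 2 gave 1163, in place of 3938. The other settings gave 2944 to 5192, and leaving out 1 library gave 3112 to 4937. For DDLPS against WDLPS, the DESeq2 test gave 1739, voom 2150 and the test against a fold change of 2 gave 257, in place of 912. The other settings gave 783 to 931, and leaving out 1 library gave 635 to 1146. The share of changed genes that were higher was 64.5% in WDLPS against normal fat, 51.6% with voom and 76.9% with the covariate. It was 43.1% in DDLPS against normal fat and 53.2% with voom. In DDLPS against WDLPS it was 31%, 43.2% with the DESeq2 test and 12.8% with the test against a fold change of 2.

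Camera called 23, 17 and 18 lists in the 3 comparisons with the preset correlation. Other splits of the same samples gave a median of 9, 12 and 12 lists at that setting. Many such calls could thus arise from arbitrary groups. With an estimated correlation camera called 2, 3 and 1, and fry called 7, 14 and 11. The 2 in WDLPS against normal fat were the amplicon and window lists, which share genes. A prior count of 0.5 left 3 of 5 list scores past the threshold in WDLPS against normal fat, and those of macrophages and p53 targets lost their calls (adjusted p = 0.0655 for each). In DDLPS against normal fat, 18 scores passed, 12 with z-scores (without p53 targets, adipose progenitors, pericytes and smooth muscle, skeletal muscle, epithelium and mesothelium, and Schwann cells and nerve) and 15 with a prior count of 0.5 (without adipose progenitors, pericytes and smooth muscle, and skeletal muscle). In DDLPS against WDLPS, 8 passed and 7 under each, without hypoxia and glycolysis. With 4 normal fat samples for each comparison, a median of 6 genes was called in both tumour types in place of 31. Over the named genes and single libraries left out, 346 calls were lost and 81 were gained, while 7157 values, of called and uncalled genes, kept their side of the threshold. At this number of samples and spread, 7.69% or fewer of simulated log2 changes of 1 were recovered, so many small changes may be missed. The simulations changed few genes, which makes the threshold stricter. In DDLPS against normal fat 3938 genes passed. Of these, 1512 higher and 1967 lower genes had a log2 change of at least 1, and the others passed with smaller changes.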

Other observations

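ZIC1, ZIC4, GRIN2D and F13A1, and the count of libraries at the end, were chosen for this part after their values were seen. Developmental transcription factors of the ZIC pair on chromosome 3 were higher on average in both tumour types. ZIC1 rose from 0.117 ± 0.251 CPM in normal fat to 7.67 ± 8.07 CPM in WDLPS (log2 fold change 6.30, SE 1.23, adjusted p = 0.0272) and 25.1 ± 16.8 CPM in DDLPS (8.01, SE 1.31, adjusted p = 0.000119). ZIC4, its neighbour, had 0 reads in normal fat and was at least 141-fold higher in WDLPS and at least 370-fold higher in DDLPS. These bounds cover counting error only and not the spread between libraries. GRIN2D, a glutamate receptor subunit, rose by 5.37 (adjusted p = 0.0231) in WDLPS and by 4.99 (SE 0.99) in DDLPS.

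F13A1, a transglutaminase made by resident tissue macrophages, rose from 189 ± 84.6 CPM in normal fat to 811 ± 457 CPM in WDLPS (2.10, SE 0.42, adjusted p = 0.0291) and 528 ± 264 CPM in DDLPS (1.48, SE 0.41, adjusted p = 0.0108). It was not a member of the macrophage list. All 3 of MDM2, CDK4 and HMGA2 lay above the highest normal fat library in 5 of 8 WDLPS and 7 of 8 DDLPS libraries.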
